A study of Mus musculus with 6 samples.

How the data were processed

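Gastrocnemius RNA was sequenced by the authors in 6 libraries, 3 of control mice (Mck cre) and 3 of mice that also carried a Glut1-Hk2-Pfkfb3 transgene, per the labels. Groups and replicate numbers were taken from the sample titles and the genotype label. Per the labels' protocols, RNA was extracted with Trizol and 3 µg per sample went into an NEBNext Ultra library. The labels give no sex, litter, batch or sequencing date. They do not say that the 3 libraries of a group come from separate animals, so p-values measure the spread between these samples.

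Per the submitters' processing notes, the tools were HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the genome build was GRCm38. The notes give the tools no role or order, and the strand setting and annotation release are not given in the sources used here. Genes that overlap, antisense genes and genes with near-identical copies can share or lose reads in such counts, and are named as uncertain where they matter. The deposited counts are whole numbers per Ensembl gene, per the file headers. The deposited FPKM values equal the counts divided by gene length and by a library size which, from the values, is the median-of-ratios size factor times the geometric mean of the library totals. Both tables held 54532 genes, 28128 of them with at least 1 count, and no row without a gene. Coordinates and biotypes are those of the deposited table. The species and sequence of the transgene are not given in the sources used here, so reads of a transgene count at the mouse gene only where its sequence matches.

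Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter and the quasi-likelihood test with legacy = FALSE, which left 14973 genes. The SE of a log2 fold change is the size of the fold change divided by the square root of its F statistic, and 95% intervals use the test's degrees of freedom. P-values are two-sided and adjusted by the Benjamini-Hochberg method at a threshold of 0.05. CPM values use the TMM library sizes. The error printed after a log2 fold change is its SE, and all other errors are SDs over 3 libraries unless given as SE. A count of 3 in a library corresponds to 0.120 to 0.145 CPM, and intervals and floors from counts cover counting error only.

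Gene lists, 47 in all, were written before the data were examined and cover glucose and energy metabolism, stress responses, muscle fibre state, cell types and technical signals. The 42 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Of the 7 lists past the threshold none passed with an estimated correlation, where adjusted p-values ran from 0.474 to 0.984. Correlation alone does not account for this. In the satellite cell list the estimate, -0.03, lay below the preset 0.01, yet the unadjusted camera p went from 2.08e-05 to 0.0113. Failing in that form therefore does not show that a call was owed to genes varying together. In 9 lists, none past the threshold, the median or mean log2 fold change and the test had different signs. Named genes followed a rule fixed at the same time. It took Slc2a1, Hk2 and Pfkfb3, and the sex-linked list in full. It also took the 12 highest and 12 lowest log2 fold changes past the threshold among protein-coding genes with a mean of at least 2 CPM, a symbol that is not a Gm or Rik name and no overlap between groups. Of each list described, it took up to 4 members past the threshold, or the 2 with the smallest p where none passed. Some genes that the rule or the families took are not reported here. Outside the rule, Gapdh, Gm28438, Dsp, Slc2a5 and the members of the families put together afterwards were named after their values were seen. The lymph node genes were chosen after the lymphocyte signal and before their own values were seen.

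The steps were tested on simulated counts for the same libraries, with 200 genes changed. Of 50 genes changed at each size, edgeR recovered 3 at 1.5-fold, 25 at 2-fold, 48 at 4-fold and 49 at 8-fold, and 17 of its 142 calls were unchanged genes. Of the 193 calls of DESeq2 on the same counts, 49 were unchanged genes. The list test called a simulated list raised by 0.8 log2 units and 0 of 100 unchanged lists. Simulated genes varied independently, so this cannot show how often lists whose genes vary together are called. In the 7 real lists past the threshold the estimated correlation ran from -0.03 (satellite cell) to 0.66 (mitochondrial transcripts). Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, limma on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, fits without each library and a fit with the replicate number as a block. Lists were also tested with fry of limma. A further 3 fits, and a list test without mt-Nd3, were added after the data were seen.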

Results

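Messenger RNA was profiled by sequencing in gastrocnemius, a fast-twitch calf muscle, of 3-month-old C57BL/6J mice given 0.2% doxycycline in the drinking water from 4 weeks of age. The 3 control libraries came from mice carrying a muscle creatine kinase Cre driver (Mck cre), and the other 3 from mice carrying the same driver and a transgene named for Glut1, Hk2 and Pfkfb3. The deposited table held whole-number counts for 54532 genes, with totals from 19546456 to 24665024 counts per library. Control replicates 1, 2 and 3 had 21796564, 24137800 and 24665024 counts, and transgenic replicates 1, 2 and 3 had 23381569, 19546456 and 23340923. After the filter on low counts 14973 genes were tested. Xist, the RNA of the inactive X chromosome, lay between 215 and 268 CPM in all 6 libraries. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in each, and Tsix had 1 count in transgenic replicate 1 and 0 elsewhere.

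The genes named in the transgene were examined first, because they check the group labels. None of the 3 passed the test between the groups. Pfkfb3, which makes the allosteric activator of phosphofructokinase, averaged 1087 ± 503 CPM in the control libraries and 379.5 ± 227 CPM in the libraries labelled transgenic (SD, n = 3 each). Every library labelled transgenic lay below every control library. Its log2 fold change was -1.52 ± 0.57 (SE, 95% interval -2.85 to -0.19), with an edgeR adjusted p of 0.196. Its two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. Slc2a1, which encodes the glucose carrier GLUT1, averaged 16.0 ± 6.30 CPM in controls and 10.4 ± 2.79 CPM in the libraries labelled transgenic. Its log2 fold change was -0.63 ± 0.31 (interval -1.34 to 0.08, adjusted p = 0.290, exact permutation p = 0.3). Hk2, the insulin-responsive hexokinase of muscle, averaged 169 ± 16.1 CPM in controls and 230.3 ± 96.1 CPM in the libraries labelled transgenic. Its log2 fold change was 0.44 ± 0.27 (interval -0.18 to 1.07, adjusted p = 0.381, exact permutation p = 0.4). The Hk2 difference came from transgenic replicate 1, at 341 CPM, since replicates 2 and 3 had 168 and 182 CPM against 156 to 187 CPM in controls. Without that library the log2 fold change of Hk2 was 0.06 (adjusted p = 0.843). The mouse genes lie on GRCm38 at chromosome 2, 11471433 to 11554077 (Pfkfb3, ENSMUSG00000026773), chromosome 4, 119108711 to 119137983 (Slc2a1, ENSMUSG00000028645), and chromosome 6, 82725025 to 82774454 (Hk2, ENSMUSG00000000628). Because none of these genes passed as higher, and Slc2a1 and Pfkfb3 had lower means, the groups are named as the labels name them. Every direction is drawn between libraries labelled transgenic and libraries labelled control.

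**Figure D1:**
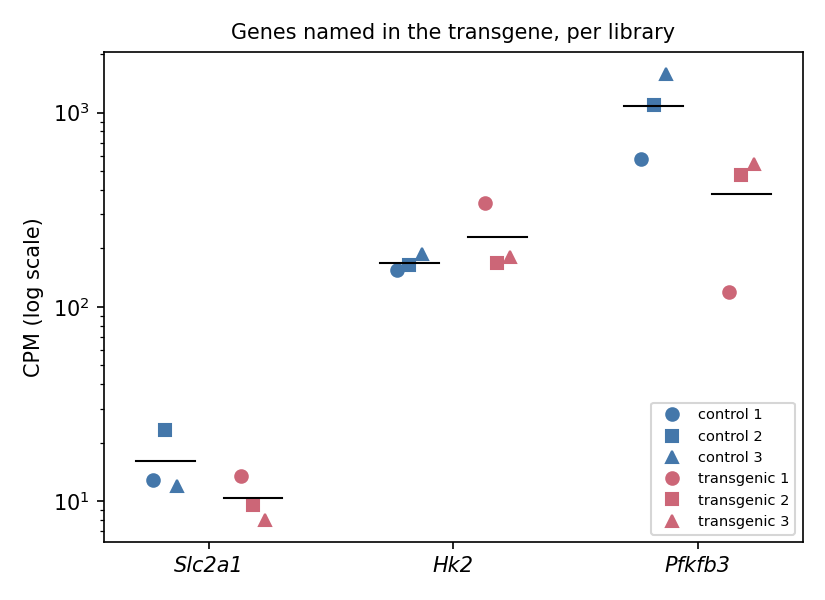
CPM on a log scale for Slc2a1, Hk2 and Pfkfb3 in each of the 6 libraries, with the mean of each group of 3 as a line. Pfkfb3 lies between 120 and 542 CPM in the libraries labelled transgenic and between 579 and 1585 CPM in the control libraries.

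Between the groups 194 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 118 higher and 76 lower in the libraries labelled transgenic. The highest of the genes named by rule were Slc15a5, an orphan member of the proton-coupled oligopeptide transporter family, Qprt, an enzyme of NAD synthesis from tryptophan, and Sln, sarcolipin, the small peptide that binds the sarcoplasmic reticulum calcium pump. Slc15a5 (ENSMUSG00000044378, chromosome 6, 137983586 to 138079916) had 2, 1 and 1 counts in the control libraries and a mean of 6.14 ± 1.89 CPM in the libraries labelled transgenic. The ratio of pooled counts was 102, with an exact counting interval from 39.7 to 378 (edgeR adjusted p = 0.00120). Qprt (ENSMUSG00000030674, chromosome 7, 127107114 to 127122226) went from 1.01 ± 0.919 to 52.7 ± 13.0 CPM (log2 fold change 5.67 ± 0.55 SE, adjusted p = 0.0188). Sln (ENSMUSG00000042045, chromosome 9, 53850164 to 53854560) went from 2.42 ± 0.551 to 78.5 ± 50.7 CPM (5.02 ± 0.67, adjusted p = 0.0250). The remaining 9 of the 12 highest were Ttc25, Smoc1, BC067074, Slc35g1, Ppp1r3b, Pald1, Dusp4, Eda and Smpdl3b, with log2 fold changes from 3.31 for Ttc25 to 2.01 for Smpdl3b. Among these, Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, rose from 0.850 ± 0.432 to 4.28 ± 0.860 CPM. Smoc1, a secreted calcium-binding matrix protein, rose from 4.43 ± 1.69 to 30.9 ± 10.8 CPM, and Dusp4, a MAP kinase phosphatase, from 4.67 ± 0.543 to 19.1 ± 6.07 CPM.

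The lowest of the genes named by rule was Mettl21e (ENSMUSG00000046828, chromosome 1, 44204070 to 44218961), a muscle lysine methyltransferase, which fell from 15.7 ± 5.19 to 1.73 ± 0.425 CPM (log2 fold change -3.16 ± 0.33 SE, adjusted p = 0.0188). Fgfbp1, a carrier of fibroblast growth factors, fell from 8.03 ± 1.37 to 1.20 ± 0.627 CPM (-2.75 ± 0.38, adjusted p = 0.0289). Car3 (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523), the abundant carbonic anhydrase of slow fibres and fat, fell from 2977 ± 534 to 994 ± 158 CPM (-1.58 ± 0.25, adjusted p = 0.0375). The other members of the 12 lowest were mt-Nd3, Kcnip2, Sorbs2, Nrep, Asb15, Mdga1, Pde4b, Kcnab1 and Sntb1, with log2 fold changes from -2.47 for mt-Nd3 to -1.54 for Sntb1. Pde4b, a cyclic AMP phosphodiesterase, fell from 176 ± 34.8 to 45.5 ± 15.7 CPM. The potassium channel partners Kcnip2 and Kcnab1 fell from 3.81 ± 0.342 to 0.695 ± 0.133 CPM and from 4.32 ± 1.25 to 1.38 ± 0.0483 CPM. The value of mt-Nd3 is uncertain, because a nuclear copy, Gm28438, shares its sequence and moved the other way.

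**Figure D2:**
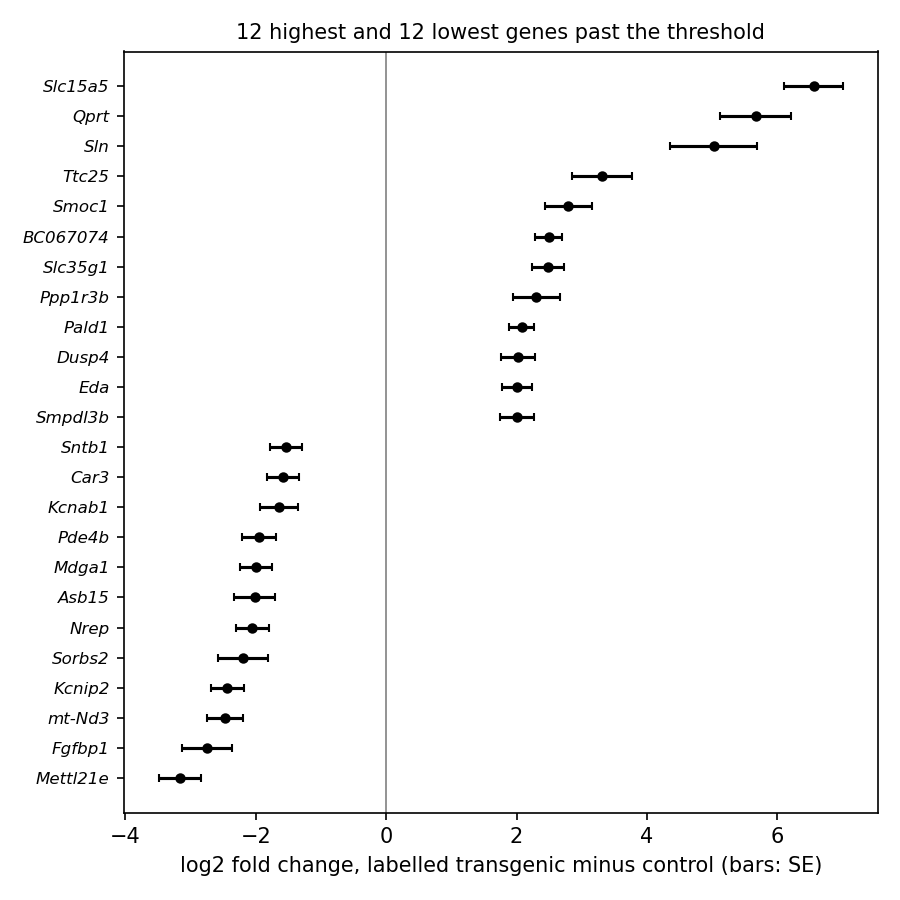
Log2 fold change of the 12 highest and 12 lowest named genes, libraries labelled transgenic minus control, with the SE as bars (n = 3 per group). Values run from 6.56 for Slc15a5 to -3.16 for Mettl21e.

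The count of 194 moved with single libraries. Control replicate 1 stood apart, with correlations of 0.947 to 0.961 with the other 5 libraries, against 0.962 to 0.988 among those. Without it edgeR's test gave 1956 genes, 910 higher and 1046 lower, and these held all 194. It gave 3 genes without control replicate 2 and 0 without control replicate 3, where 2116 had an unadjusted p under 0.05. Without transgenic replicates 1, 2 and 3 it gave 54, 1 and 1. Of the 24 genes named by rule, 24, 3, 0, 14, 1 and 1 passed in these 6 fits. All 24 kept their direction in each, but genes chosen for no overlap between groups could hardly change it. DESeq2 called 1075 genes, but on the simulated counts 49 of its 193 calls were unchanged genes. Scaling by library totals alone gave 205 higher and 54 lower, a share of 79.2% higher in place of 60.8%, with the median log2 fold change of all genes at 0.12 in place of -0.03. The 3 and 3 CPM values did not overlap in 4104 of the 14973 genes, or 27.4%, where chance gives 10%.

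Lymphocyte genes set control replicate 1 apart from the other 5 libraries. The 9 genes of the B cell list summed to 559 CPM in that library and to 7.31 to 60.6 CPM in the others, and the 15 genes of the T and NK cell list to 159 CPM against 1.15 to 7.42 CPM. Igkc, an immunoglobulin light chain, was at 109 CPM there and Cd4 at 17.2 CPM, against at most 10.4 and 0.776 CPM elsewhere. With fewer than 5 members kept by the filter, the B cell, T and NK cell and neutrophil lists had no list test. None of Cd2, Cd4, Igkc, Ighm, Mmp9 and Csf3r passed the threshold between the groups in edgeR. The log2 fold change of Cd4 was -3.48 ± 1.70 with all libraries and turned to 3.33 without control replicate 1 (adjusted p = 0.0350). The latter rests on 1 count in each of control replicates 2 and 3, under the 3-count floor. Transgenic replicates 1, 2 and 3 had 13, 16 and 7 counts. The 9 neutrophil genes summed to 13.5 CPM in control replicate 1 and to 1.42 to 5.24 CPM in the others. Gapdh, which shares sequence with many pseudogenes and is therefore uncertain, was at 16.7 CPM in control replicate 1, at 231 CPM in transgenic replicate 3 and between 648 and 682 CPM in the other 4 libraries.

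**Figure D3:**
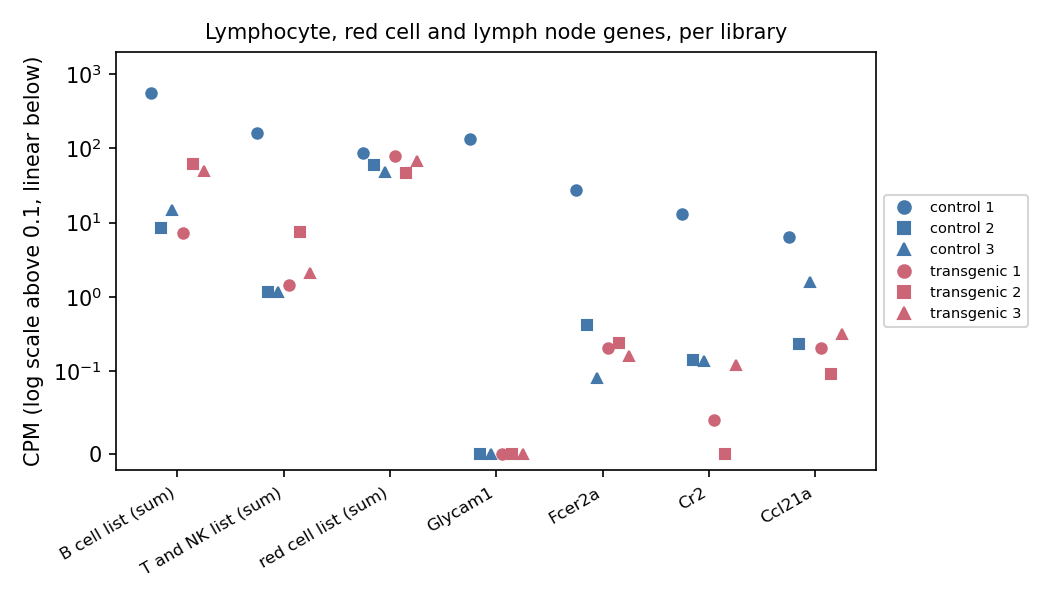
CPM per library of the summed B cell, T and NK cell and red cell lists and of 4 genes chosen for lymph node, on an axis that is logarithmic above 0.1 and linear below. Of these genes, Cr2 and Fcer2a are also B cell genes. Control replicate 1 lies above every other library in the B cell and T and NK cell lists and in the 4 genes, among which Ccl21a had the lowest ratio to the next library, 4.07.

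Metabolic lists were tested next, because the transgene names steps of glucose uptake and glycolysis. Of 17 glycolytic enzymes 3 passed as higher without control replicate 1, and none passed the threshold over all genes with all libraries. Adjusted over the list alone 1 was higher, Gpi1, an isomerase early in glycolysis, at 998 ± 174 CPM in controls and 1854 ± 132 CPM in the libraries labelled transgenic (log2 fold change 0.89 ± 0.21, adjusted p = 0.0847 over all genes). The glycolysis list as a whole did not pass (camera adjusted p = 0.385), and its second-ranked member, Eno1, had a log2 fold change of 0.28 ± 0.13. Among 21 genes of glycogen metabolism 1 fell, Epm2a, which encodes the glycogen phosphatase laforin, from 108 ± 17.0 to 60.7 ± 4.02 CPM (-0.83 ± 0.14, adjusted p = 0.0463), with 1 higher and 1 lower adjusted over the list alone. In the polyol and hexosamine list 1 of 10 genes rose, Sord, sorbitol dehydrogenase, from 72.6 ± 2.99 to 117 ± 10.2 CPM (0.69 ± 0.11, adjusted p = 0.0410), with 3 higher and 1 lower adjusted over the list alone. In the ChREBP and lipogenesis list 1 of 19 rose, Acaca, acetyl-CoA carboxylase 1, from 16.3 ± 3.72 to 61.1 ± 3.17 CPM (1.91 ± 0.17, adjusted p = 0.0182), with 2 higher and 1 lower adjusted over the list alone. None of 24 genes of glucose uptake and insulin signalling passed over all genes, and 3 were higher and 4 lower adjusted over the list alone. In the fit without control replicate 1 this list had 2 genes higher and 4 lower over all genes. Akt1 was at 0.84 ± 0.15 (adjusted p = 0.0518) and Slc2a3 at -1.04 ± 0.20 (0.0603). The 4 lists just named had camera adjusted p-values of 0.815, 0.294, 0.578 and 0.643.

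The list of 13 mitochondrially encoded mRNAs was lower in the libraries labelled transgenic (camera adjusted p = 0.00165). The log2 fold change was negative in 13 of 13, with a median of -0.48. Past the threshold over all genes, and adjusted over the list alone, was 1 gene, mt-Nd3. Its own direction is uncertain, since mt-Nd3 summed with its nuclear copy Gm28438 had a log2 ratio of group means of 0.051 ± 0.38. The other 12 lay between -0.67 and -0.16, and without mt-Nd3 the list had adjusted p = 0.00932. Among these 12, mt-Co2, mt-Atp6, mt-Co3, mt-Nd4l and mt-Nd4 also have nuclear copies that took counts, so their values are uncertain too. The mean share of the copy ran from 0.911% (mt-Nd4) to 27.3% (mt-Co2) in controls. In the libraries labelled transgenic it ran from 1.05% (mt-Nd4) to 23.0% (mt-Co3). With an estimated correlation the list had adjusted p = 0.984, with and without mt-Nd3. The per-library median of all 13 was lowest in transgenic replicates 2 and 3 and lay within the control range in transgenic replicate 1. The 34 nuclear genes of oxidative phosphorylation did not pass (adjusted p = 0.187), with 0 members past the threshold and Cox8b at -0.78 ± 0.19 and Cox6a2 at -0.65 ± 0.18. That list was lower without control replicate 1 (adjusted p = 0.0227, and 0.879 as the adjusted p with an estimated correlation) and without transgenic replicate 1 (adjusted p = 1.78e-08). The TCA cycle and lactate lists, at adjusted p = 0.591 and 0.382, were also lower without transgenic replicate 1 (0.00407 and 0.00767). Without that library all 3 lists had adjusted p = 0.960 with an estimated correlation. In transgenic replicate 1 the per-library medians of these 3 lists, in the order named, were 0.41, 0.35 and 0.35. They lay above every control library, where the highest were 0.19, 0.19 and 0.17. In transgenic replicates 2 and 3 they lay below every control library, so the libraries labelled transgenic did not move one way. The NRF2 antioxidant list was lower (camera adjusted p = 0.0217, and adjusted p = 0.984 with an estimated correlation), with 2 of 22 genes past the threshold and 6 lower adjusted over the list alone. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, fell from 38.3 ± 5.28 to 17.7 ± 2.35 CPM (-1.11 ± 0.16, adjusted p = 0.0289). The glutathione transferase Gsta4 fell from 7.99 ± 0.513 to 3.90 ± 0.155 CPM (-1.03 ± 0.17, adjusted p = 0.0410). The call of this list was lost without control replicate 2 (adjusted p = 0.0679), control replicate 3 (0.0590) and transgenic replicate 1 (0.0909). The polyamine and growth list was lower (camera adjusted p = 0.0109, and adjusted p = 0.984 with an estimated correlation), with 0 of 16 genes past the threshold over all genes and 5 lower and 1 higher adjusted over the list alone. Odc1, ornithine decarboxylase, had a log2 fold change of -1.66 ± 0.35 (adjusted p = 0.0707) and Fbl, fibrillarin, -0.50 ± 0.13. Without transgenic replicate 1 this list had adjusted p = 0.0502.

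Markers of satellite cells, the muscle stem cells, were higher in the libraries labelled transgenic (camera adjusted p = 8.72e-04, and adjusted p = 0.474 with an estimated correlation). Of the 10 markers tested, 7 had a positive log2 fold change, and 2 passed as higher over all genes. Calcr, the calcitonin receptor, rose from 0.374 ± 0.0421 to 1.63 ± 0.200 CPM (log2 fold change 2.10 ± 0.31, adjusted p = 0.0324). Its counts in control replicates 1, 2 and 3 were low, at 9, 7 and 9. Itga7, an integrin that muscle fibres also express, rose from 64.4 ± 2.03 to 121 ± 22.3 CPM (0.91 ± 0.15, adjusted p = 0.0406). Adjusted over the list alone 6 were higher and 0 lower, and the call held without each library in turn, with adjusted p-values from 3.25e-04 to 0.00650. In those fits the adjusted p with an estimated correlation ran from 0.785 to 0.960. By fry, with all 6 libraries, this was the only list past the threshold (adjusted p = 0.00690). The lists of extracellular matrix (27 of 30 genes with a positive log2 fold change, camera adjusted p = 0.00213), fibro-adipogenic progenitors (11 of 13, 0.00962) and smooth muscle and pericytes (9 of 10, 0.0109) were also higher. Each had 0 members past the threshold over all genes and adjusted p = 0.984 with an estimated correlation. Adjusted over the list alone, 0, 3 and 5 of their genes were higher. Col5a2 had a log2 fold change of 0.62 ± 0.19 and Col4a2 1.01 ± 0.32. Those of the progenitor markers Pdgfra and Cxcl14 were 0.78 ± 0.20 and 1.08 ± 0.28, and those of Notch3 and Myh11 0.81 ± 0.20 and 0.66 ± 0.17. Transgenic replicate 1 had the highest per-library median of the matrix and smooth muscle lists, and control replicate 2 the lowest of these 3 lists. In the matrix list the remaining libraries overlapped, with control replicates 1 and 3 at 0.073 and -0.074 and transgenic replicates 2 and 3 at -0.021 and 0.088. The 13 endothelial genes, at adjusted p = 0.0589 with all 6 libraries and no replicate block, also had their highest per-library median in transgenic replicate 1, and the list was higher without transgenic replicates 2 (0.00924) and 3 (0.00970). The adjusted p with an estimated correlation was 0.974 and 0.955 in these fits. The calls of matrix and progenitors were lost without control replicate 2 (adjusted p = 0.144 and 0.147), and that of smooth muscle without control replicate 1 (0.0518), control replicate 2 (0.0679) and transgenic replicate 1 (0.0623).

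**Figure D4:**
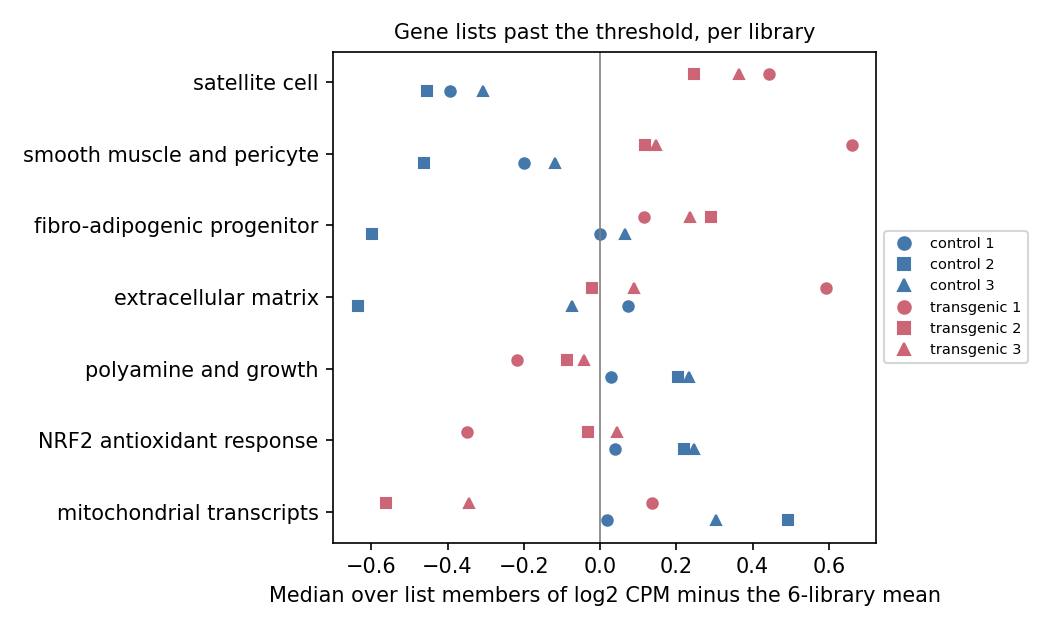
For each of the 7 lists past the threshold, the median over list members of log2 CPM minus the mean of the 6 libraries, 1 point per library. The satellite cell list separates the groups, from -0.45 to -0.31 in controls and 0.25 to 0.44 in the libraries labelled transgenic.

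The fibre-type and wasting lists did not pass with all 6 libraries, TMM scaling and no replicate block. With scaling by library totals alone the fast fibre and atrophy lists were lower (adjusted p = 0.0401 and 0.0310, and 0.985 for both as the adjusted p with an estimated correlation). The 16 fast fibre genes had adjusted p = 0.0890, with Casq1 at -0.76 ± 0.18 and Myoz1 at -0.63 ± 0.23. The 22 atrophy genes also had adjusted p = 0.0890, with 5 lower adjusted over the list alone. Among them Mstn, myostatin, was at -2.81 ± 0.59 (adjusted p = 0.0721), with 146 ± 95.6 CPM in controls and 20.8 ± 4.61 CPM in the libraries labelled transgenic. Both lists were lower without control replicate 1 (adjusted p = 0.0180 and 2.04e-04, and 0.825 for both as the adjusted p with an estimated correlation), where 8 atrophy genes fell. The atrophy median of that control, -0.39, lay below every library labelled transgenic (-0.29 to -0.001). Its fast fibre median, -0.14, lay within their range (-0.38 to -0.06). Mstn was at 36.1 CPM in control replicate 1 and at 201 and 202 CPM in control replicates 2 and 3. The fast fibre list was also lower without transgenic replicate 2 (0.0359) and the atrophy list without transgenic replicate 3 (0.0429), with 0.974 and 0.955 as the adjusted p with an estimated correlation. In the slow fibre list 1 of 15 genes passed, Sln, and the list had adjusted p = 0.968. The interferon list had adjusted p = 0.0878 with all libraries and no replicate block, and its per-library median was highest in control replicate 1, at 0.73. It was higher without control replicate 1 (1.46e-06, and 0.825 as the adjusted p with an estimated correlation) and without transgenic replicates 2 (0.0465) and 3 (0.0294), where the adjusted p with an estimated correlation was 0.974 and 0.956. Of its 25 genes 0 passed with all libraries, with Rsad2 at 0.93 ± 0.29 and Oasl2 at 0.69 ± 0.32, and 3 without control replicate 1. Without that library the macrophage list was higher (0.0112 in place of 0.187) and the p53 list lower (0.0476 in place of 0.290), with adjusted p = 0.825 for both with an estimated correlation. Control replicate 1 had the highest macrophage median of the 6 libraries, 0.46. Its p53 median, -0.17, lay within the range of the libraries labelled transgenic (-0.19 to -0.05). In the technical lists 1 of 14 immediate early genes passed, Jun, which fell from 202 ± 56.6 to 82.2 ± 11.9 CPM (-1.30 ± 0.22, adjusted p = 0.0463), and 0 of 16 clock genes, with Cry1 at -0.76 ± 0.14 and Nr1d1 at 0.68 ± 0.16. These 2 lists had adjusted p = 0.353 and 0.274. With all 6 libraries, TMM scaling and no replicate block, 35 of the 42 lists tested did not pass, with adjusted p-values from 0.0589 to 0.983.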

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

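The fits with edgeR's robust option, with limma-voom sample weights and without both libraries numbered 1, and the list test without mt-Nd3, were chosen after the data were seen, and all others before. Hk2 and the 24 genes at the extremes kept their signs under every alternative that gave them a value, and Pfkfb3 and Slc2a1 stayed negative. For the 24 this was close to fixed by the rule of no overlap between groups. Of them 24 passed by DESeq2, 20 by limma-voom, 2 with the replicate block and 0 by limma on unfiltered log2(FPKM + 1). Genes called numbered 194, with 118 higher and 76 lower. In the same order they were 1075, 595 and 480 by DESeq2, 124, 84 and 40 with no low-count filter, and 1, 1 and 0 at an adjusted p under 0.01. By limma on unfiltered log2(FPKM + 1) they were 0, 0 and 0, with 3303 genes at an unadjusted p under 0.05. Library totals alone gave 205 higher, and limma on filtered log2(FPKM + 1) 50 lower. Leaving out 1 library gave 0 to 1956 genes, 0 to 910 higher and 0 to 1046 lower. Sample weights gave 3796, 1730 and 2066, and the fit without both libraries numbered 1 gave 3269, 1569 and 1700, each with all 194 among them. There the log2 fold change of Pfkfb3 passed at -1.56 and -1.38, and the log2 fold change of Slc2a1 passed in the latter at -0.98. Of 31 biology lists 4 passed, against 6 with library totals alone (fast fibre and atrophy added), 7 with the replicate block (fast fibre, atrophy and interferon added), 12 without both libraries numbered 1, 0 with an estimated correlation, 0 by fry and 2 to 9 without 1 library. Of 11 cell type and technical lists 3 passed, against 4 with the replicate block (endothelial added), 4 without both libraries numbered 1, 0 with an estimated correlation, 1 by fry and 1 to 4 without 1 library. With an estimated correlation no list passed in the block fit (lowest adjusted p 0.963) or without both libraries numbered 1 (lowest 0.648) either. The log2 fold change of Cd4 ranged from -4.05 to 3.33 without 1 library and was 3.31 without both libraries numbered 1, where the log2 fold change of Ighm was 2.28 and the fatty acid oxidation list passed in the other direction (adjusted p = 0.00823, and adjusted p = 0.831 with an estimated correlation). The Cd4 values of 3.33 and 3.31 rest on 1 count in each of control replicates 2 and 3. Short of the threshold, 18 of 2111 gene values and 45 of 588 list values changed sign. Except where an alternative itself tests more genes, uses fewer libraries or sets a stricter threshold, the cause was not tested. The replicate block left 5 genes, 2 higher and 3 lower. Same-numbered libraries did not deviate together (correlations -0.02, -0.17 and 0.16), and not every library correlated best with its own number. With so few libraries this cannot exclude that the numbers pair the samples. At these depths 25 of 50 simulated 2-fold changes were recovered.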

Other observations

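The families in this paragraph were put together after their genes were seen among those past the threshold, so their tests are not independent evidence. Splicing factors of the SR family were lower in the libraries labelled transgenic, with 12 of 12 log2 fold changes negative, 11 of 12 when scaled by library totals alone, a median of -0.60 and 5 genes past the threshold (camera p = 9.57e-09, p = 0.0374 with an estimated correlation). Srsf3 fell from 90.1 ± 8.60 to 41.3 ± 0.372 CPM (edgeR adjusted p = 0.0188, n = 3 each) and Tra2b from 48.5 ± 0.274 to 27.1 ± 1.02 CPM (adjusted p = 0.0210). Genes of branched-chain amino acid and propionate breakdown had negative values in 21 of 23 members, 19 when scaled by library totals alone, and Pccb, Bckdhb and Mmab fell (camera p = 1.74e-07, p = 0.211 with an estimated correlation). Basement membrane genes had positive values in 22 of 22 members, and Hspg2, Lama2 and Lamc1 rose (camera p = 1.00e-10, p = 0.101 with an estimated correlation), Hspg2, perlecan, from 148 ± 16.3 to 341 ± 77.1 CPM. Among integrins 3 of 19 rose, Itgav, Itga3 and Itga7, and the family had 14 positive and 5 negative log2 fold changes (camera p = 0.00190, p = 0.211 with an estimated correlation). Among 23 potassium channel genes and partners Kcnc4, Kcnv2, Kcnab1 and Kcnip2 fell, and the family as a whole did not move one way (12 negative and 11 positive log2 fold changes, 11 and 12 when scaled by library totals alone, camera p of 0.489). Also near absent from the control libraries were Dsp, desmoplakin, with 2.08 ± 1.43 CPM in the libraries labelled transgenic, and Slc2a5, the fructose carrier GLUT5, with 1.05 ± 0.194 CPM (edgeR adjusted p = 0.0188 for both).

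Of the tests below, those of the transgene's genes, of the red cell genes and of mt-Nd3 were chosen after their values were seen, and those of the lymph node genes, the chromosome positions and the splits of the libraries before. None of the genes named in the transgene passed as higher in the libraries labelled transgenic, although the interval of Hk2, up to 1.07, leaves a rise of that gene open. A lift of all 3 mouse genes by transgene reads was taken to need all 3 intervals above 0, and the upper 95% limit of Pfkfb3 was -0.19. That limit, not adjusted for the number of genes tested, concerns Pfkfb3 alone. With so few libraries a real lift can leave an interval spanning 0, so the test does not decide for Hk2 or Slc2a1. Exchanged group labels would need all 3 genes lower in the libraries labelled transgenic, and the highest lower limit, that of Hk2, was -0.18, with its interval spanning 0, so exchanged labels and correct labels cannot be told apart from these genes. Also open and untested are a transgene whose sequence is not counted at the mouse genes, and a transgene that was not expressed in these muscles.

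Control replicate 1 carried lymphocyte transcripts, and a candidate explanation is lymphoid tissue collected with the muscle, since a lymph node lies behind the knee beside this muscle. Of 6 genes of lymph node vessels, stroma and follicles chosen before their values were seen, 6 were at least 4 times as high there as in any other library, with a floor of 3 counts per library. Cr2 and Fcer2a are also B cell genes. The B cell signal of this library was already known, so they do not tell a lymph node from other B cells. Glycam1, made by lymph node venules, was at 135 CPM (3231 counts) with 0 counts in the other 5 libraries, Fcer2a at 27.3 CPM and Cr2 at 13.2 CPM, while Ccl21a and Madcam1 passed narrowly, at 4.07 and 4.02 times. Blood left in the muscle would bring red cell transcripts, but 6 red cell genes differed by a median of 0.46 log2 units against 5.41 for the 5 lymphocyte genes tested. No biological explanation was tested, because the labels set this mouse apart in nothing.

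The fall of mt-Nd3 came with a rise of its nuclear copy Gm28438 (chromosome 1, 24612775 to 24613119). The copy took 16.1 ± 2.38% of the counts of the pair in the control libraries and 85.4 ± 0.380% in the libraries labelled transgenic (SD, n = 3 each), and over 345 aligned bases the reference sequences differ at 1, T3C (mt-Nd3 base first, counted from 1 at its 5′ end; mitochondrial position 9461). The 2 genes summed had a log2 ratio of group means of 0.051 ± 0.38 (SE), which failed the test as first set, the bare range of -0.67 to -0.16 of the 12 other mitochondrial mRNAs, and passed a revised test, set after that outcome, that widened the range by 1 SE. Fewer mitochondrial transcripts overall would not do it, since the lowest of those 12 was -0.67 against -2.48 for mt-Nd3. Nuclear copies took counts of some of those 12 as well, so their range is itself uncertain. Both reference sequence and counts are consistent with a mitochondrial sequence difference between the mice of the 2 groups that moves reads to the copy, but with a test revised in this way, and with the reads not analysed here, this stays a hypothesis.

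DNA of another strain carried along with the transgenes could place genes past the threshold in clusters. Of 191 such genes on the nuclear chromosomes, 57 had another within 1 Mb, against 33 to 64 in 95% of 10000 random draws of tested genes (one-sided permutation test, p = 0.148), so no clustering was detected at this scale. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 194 genes, and the highest of the other 9 gave 0. With 10 splits no share under 0.05 can be reached.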
